A study of Mus musculus with 84 samples.

How the data were processed

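Per-gene counts of RNA and per-peak counts of ATAC-seq and CUT&RUN were used as deposited by the authors, for 84 libraries in 42 groups of 2. The submitters' notes named STAR 2.5.0c, Picard 1.141, MACS2 2.1.1 and build GRCm38, without the role of each tool. The counting tool, its strand setting, the treatment of duplicates and of reads from the Cast allele, and the way in which the shared peak lists were made are not given in the sources used here. Values were whole numbers in each column. Even values made up 61.2% of ATAC-seq counts, 60.1% of Runx1 counts and 51.7% of Tcf1 counts between 1 and 20, against 39.8% for RNA. Groups were taken from the labels (assay, antibody, lineage, and day, with day 7 as activated and day 60 as memory). The F1 mice carry Cast alleles.

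Each assay, and each antibody of CUT&RUN, was fitted with all its libraries in edgeR 4.0.16 on R 4.3.3: filterByExpr, TMM scaling, quasi-likelihood dispersion and quasi-likelihood F tests, with Benjamini-Hochberg adjustment over the genes or peaks of a comparison and a threshold of 0.05. Of 47069 gene identifiers 18854 were tested, and 46488 had a symbol. Peaks tested numbered 50807 of 52004 for ATAC-seq and between 5349 (Nfatc1) and 34661 (Runx1) for the antibodies. RNA and ATAC-seq had 10 comparisons each: activated and memory against naive and memory against activated within CD4 and CD8 cells, CD8 against CD4 cells at each stage, and the interaction of lineage and activation. Runx1, Tcf1 and Ets1 had 4 comparisons each and the other 9 antibodies 1 each. Levels were CPM on library sizes scaled by TMM, as mean ± SD of n = 2, and errors of log2 fold changes were standard errors from the fit.

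The 26 gene lists were fixed before the data were examined: profiled factors, naive and quiescence, cytotoxic effector, Th1, Tfh, inhibitory receptors, memory, cell cycle, AP-1 with NR4A and EGR, subunits of BAF, ISWI, NuRD and RUVBL1-containing remodelers, interferon stimulated, glycolysis, cholesterol synthesis, trafficking of effector cells, CD4 lineage, CD8 lineage, Treg, and markers of B cells, myeloid cells, erythroid cells and platelets, and NK and innate-like T cells, with heat shock and dissociation stress and mitochondrially encoded genes. Of 411 members 397 were tested. Each list was counted over all genes and with adjustment over the list alone, and tested with camera of limma 3.58.1 at the preset correlation of 0.01 and with an estimated correlation. Named genes were fixed by a rule before the data were examined: the 6 largest rises and 6 largest falls past the threshold in activated and memory against naive cells (4 each elsewhere), with a symbol, a mean of at least 10 CPM in the higher group, and both libraries of a group on the same side of both of the other, receptor and immunoglobulin segments left out. To these came the profiled factors and the 2 to 4 members of each list with the largest change past the threshold, or 2 where none passed, with 5 lists in place of 26 in the other comparisons. Named peaks were the 2 largest per direction with at least 5 CPM. Loci were 16 genes with 50 kb on each side. Jund, Socs1, Gm10800 and per-library values were chosen after they were seen where the rule did not name them. Some genes and peaks that the rule named are not reported here.

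Folds against a group with 0 counts were floors with 3 counts over the group, and those with 1 to 3 counts were ratios with 95% intervals of counting error. Peaks were compared by overlap of at least 1 bp, with 50% of a peak as the alternative, in GenomicRanges 1.54.1, and Fisher's exact tests of bound against gained or lost peaks (48 tests) were adjusted by Benjamini-Hochberg. Gene spans of 16363 tested genes were matched to peaks with 1000 bp on each side (5000 bp as the alternative) in place of promoters, since the gene table gave no strand. The share of peaks with a motif was not computed, since no genome sequence was at hand. Alleles were not analysed here.

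Alternatives were DESeq2 1.42.0 size factors, total counts in peaks, no filter on low counts, the DESeq2 Wald test, a replicate block, an estimated list correlation, a wider overlap and flank, and each library left out in turn, with the lone library assumed to vary like the other groups. A satellite region on chromosome 2 from 98666577 to 98667289 as the scale, and RNA without 3 libraries that stand apart, were chosen after the data were seen. The region took in peaks within 10 kb (1 for Runx1, 3 for Tcf1 and 5 for Ets1). The fit without those 3 libraries leaves a lone library in each of their groups. Their replicate differences then no longer enter the shared estimate of the spread, which by itself favours more calls. The pipeline was tested on simulated data with 200 changed features. At 4-fold it recovered 53% for RNA, 87.9% for ATAC-seq, 92.4% for Runx1 and 74.2% for T-bet. At 2-fold it recovered 14.9%, 61.2%, 64.2% and 20.9%, and at 1.5-fold 0%, 22.4%, 34.3% and 0%, in that order. Of 53, 119, 132 and 66 calls in that order, 8, 5, 5 and 3 were of features not changed. For RNA this share was above the threshold. Shared controls were simulated 20 times for RNA and 10 times for ATAC-seq. Files were read with the R package data.table, version 1.17.8.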

Results

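RNA sequencing (12 libraries), ATAC-seq (12 libraries) and CUT&RUN (60 libraries, 12 antibodies) were compared in CD4 and CD8 T cells from the spleens of F1 mice of a B6 and a Cast parent. Cells were naive, activated (day 7 of LCMV infection) or memory (day 60), and each of the 42 groups held n = 2 libraries. Counts per library were 16.3 M to 22.6 M for RNA, and in peaks 8.88 M to 16.8 M for ATAC-seq and 0.24 M to 17.4 M for CUT&RUN. Runx1, Tcf1 and Ets1 were profiled in naive and activated cells, and T-bet, Jun, Irf4, Bhlhe40, Nfatc1, Brg1, Snf2h, Chd4 and Rvb1 in activated cells alone. Changes are given as log2 fold change ± SE and levels as mean ± SD counts scaled to library size (CPM). Adjusted p values came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, unless a list test is named. The labels did not say whether replicates came from separate animals, so that p values measure the spread between these libraries. Folds against a group with 0 counts are floors, and these floors and the intervals of ratios cover counting error alone.

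The first comparison asked how the RNA of activated CD4 cells differed from that of naive CD4 cells. Gzmb, which encodes the protease granzyme B, rose by 9.89 ± 0.15 (414 ± 37.5 against 0.43 ± 0.0858 CPM). Cxcr6, which encodes a chemokine receptor, rose by 10.02 ± 0.11 (1293 ± 117 against 1.24 ± 0.12 CPM). Ifng, which encodes interferon gamma, reached 183 ± 20.1 CPM and was at least 2555-fold higher than in naive cells, where it had 0 counts. Il7r fell by 4.72 ± 0.09 (29.2 ± 3.05 against 772 ± 16.2 CPM) and Igfbp4 fell by 10.91 ± 0.32 (0.625 ± 0.167 against 1213 ± 27 CPM). Of 18854 genes tested, 4981 rose and 4554 fell. Among genes of the T helper programs, Tigit rose by 10.68 ± 0.59, Il21 by 7.15 ± 0.48 and Ctla4 by 6.81 ± 0.10 (960 ± 93.2 against 8.55 ± 0.14 CPM). Hspa1a, a heat shock gene with a near-identical copy in Hspa1b and for that reason an uncertain count, rose by 10.50 ± 0.48 (491 ± 106 against 0.328 ± 0.255 CPM).

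Gene lists were counted for activated against naive CD4 cells in the order higher and lower. Of 24 naive and quiescence genes 18 fell, among them Dapl1 and Il7r, 1 rose and 5 did not pass (20 fell and 2 rose adjusted over the list alone). All 35 cell cycle genes but 1 rose, among them Mki67 (7.44 ± 0.46) and Cdk1 (7.28 ± 0.25). Counts of the effector lists were cytotoxic effector (18 rose and 3 fell of 21), Th1 (15 rose and 0 fell of 17) and Tfh (17 rose and 1 fell of 18). Receptor and homing lists gave inhibitory receptors (11 rose and 0 fell of 12) and trafficking of effector cells (15 rose and 1 fell of 16), with Klrc1, Cxcr3, Rgs16 and Tigit as examples. Metabolic lists gave glycolysis (16 rose and 1 fell of 17), with Hk2 up by 9.69 ± 0.16 and Tpi1 by 4.40 ± 0.10, and cholesterol synthesis (8 rose and 6 fell of 20), with Fdft1 higher and Lss lower. Lists of remodeler subunits gave BAF (5 rose and 6 fell of 21, 5 and 7 adjusted over the list alone), ISWI (2 rose and 2 fell of 11), NuRD (6 rose and 1 fell of 14) and RUVBL1-containing complexes (4 rose and 3 fell of 17), with Ss18 and Mbd2 higher and Chd3 and Smarca2 lower. Further lists gave memory (7 rose and 8 fell of 16, 7 and 9 adjusted over the list alone), AP-1, NR4A and EGR (8 rose and 5 fell of 16, 8 and 6 adjusted over the list alone) and interferon stimulated genes (13 rose and 7 fell of 24, 13 and 8 adjusted over the list alone). Lineage lists gave CD4 lineage (4 rose and 1 fell of 7), CD8 lineage (5 rose and 3 fell of 10) and Treg (5 rose and 4 fell of 9). Lists that bear on the state of the cells gave heat shock and dissociation stress (11 rose and 3 fell of 15) and mitochondrially encoded genes (0 rose and 6 fell of 13). Examples were Cxcr3 and Batf (higher), Ifit1 (lower), Tnfrsf4 and Nkg7 (higher), Gpr83 (lower), Gadd45b (higher) and mt-Nd1 (lower).

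Markers of other cells in activated against naive CD4 cells were counted beside the T cell lists. B cell markers gave 7 rose and 1 fell of 10, 8 and 2 adjusted over the list alone, with Cd22 at 44 ± 5.87 CPM in activated cells and Ighm lower (392 ± 33.1 against 610 ± 22.6 CPM). Myeloid markers gave 6 rose and 2 fell of 11, 7 and 3 adjusted over the list alone, with Itgam higher (16.4 ± 0.0854 against 1.26 ± 0.155 CPM) and Lyz2 lower (18.3 ± 3.87 against 134 ± 2.24 CPM). Erythroid and platelet markers gave 0 rose and 0 fell of 4, with Hbb-bs and Hba-a1 not passing, and NK and innate-like T markers gave 3 rose and 2 fell of 7, with Klrb1c higher and Trdc lower. Of the 12 genes of the profiled factors, Bhlhe40 (9.64 ± 0.36), Tbx21 (7.09 ± 0.91), Irf4 (3.33 ± 0.19), Chd4 (0.43 ± 0.12) and Smarca4 (0.35 ± 0.12) rose, Tcf7 fell by 0.66 ± 0.09 (709 ± 46.2 against 1122 ± 46 CPM) and Jun fell by 2.41 ± 0.88 (adjusted p = 0.0486). Runx1, Ets1, Nfatc1, Smarca5 and Ruvbl1 did not pass. The Jun call ended without replicate 2 of activated CD4 cells (adjusted p = 0.188), without replicate 1 of naive CD4 cells (0.12) and without replicate 2 of naive CD4 cells (0.131), and Smarca4 and Chd4 also lost their calls when single libraries were left out (adjusted p up to 0.287 and 0.121). Without the 3 RNA libraries that stand apart, Runx1 rose by 0.63 and Nfatc1 by 0.72, and Chd4 no longer passed (adjusted p = 0.072). Nfatc1 also passed without replicate 2 of activated CD4 cells alone (adjusted p = 0.0281).

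The 26 lists were also tested with camera, with Benjamini-Hochberg adjustment over the 26 lists of a comparison. In activated CD4 cells, naive and quiescence genes were lower (adjusted p = 2.72e-10) and cell cycle genes higher (adjusted p = 1.41e-20). Higher as well were Th1 (adjusted p = 4.43e-12, adjusted p = 0.063 with an estimated correlation), Tfh (adjusted p = 2.72e-10, adjusted p = 0.0677 with an estimated correlation), cytotoxic effector (adjusted p = 1.04e-10, adjusted p = 0.084 with an estimated correlation), inhibitory receptors (adjusted p = 4.96e-09, adjusted p = 0.063 with an estimated correlation) and trafficking of effector cells (adjusted p = 1.63e-09, adjusted p = 0.0555 with an estimated correlation). Camera also called higher glycolysis (adjusted p = 1.75e-11, adjusted p = 0.145 with an estimated correlation), heat shock and dissociation stress (adjusted p = 0.000717, adjusted p = 0.063 with an estimated correlation), CD4 lineage (adjusted p = 0.0385, adjusted p = 0.345 with an estimated correlation) and B cell markers (adjusted p = 0.0385, adjusted p = 0.384 with an estimated correlation). The B cell marker call also ended without the 3 libraries that stand apart (adjusted p = 0.212), and without them the profiled factors (adjusted p = 0.0138), AP-1, NR4A and EGR genes (0.0113) and CD8 lineage genes (0.00977) passed as higher. With n = 2 per group and genes that move together, the list p values depend on the correlation that is assumed.

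The same question was put to activated against naive CD8 cells. Gzmb rose by 10.72 ± 0.15 (2723 ± 29.5 against 1.61 ± 0.0183 CPM), and Klrg1, which encodes a receptor of effector cells, by 11.46 ± 0.52 (288 ± 7.91 against 0.0954 ± 0.135 CPM). Ccr2 rose by 12.33 ± 0.44 (650 ± 20.4 against 0.12 ± 0.103 CPM). Gzmk stood at 244 ± 10 CPM in activated cells and was higher, 10160-fold (interval 1824 to 401400, 1 count in the lower group). Ccr7, which encodes a lymph node homing receptor, fell by 7.55 ± 0.09 (6.86 ± 0.328 against 1283 ± 54.8 CPM). Tcf7, which encodes Tcf1, fell by 4.58 ± 0.10 (44.9 ± 5.52 against 1073 ± 42 CPM). Tppp3 was at least 1205-fold higher than its 0 counts in naive cells, and Nfam1 was at least 354-fold lower. Itgae, which encodes integrin alpha E, fell by 5.81 ± 0.35 (3.95 ± 0.963 against 221 ± 1 CPM). Rises passed the test for 4323 genes and falls for 4502.

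Lists in activated against naive CD8 cells followed. All 21 cytotoxic effector genes rose, among them Gzmb and Cx3cr1 (adjusted p = 1.41e-21), and all 35 cell cycle genes rose, among them Ccnb2 and Birc5 (adjusted p = 8.61e-28). Of 24 naive and quiescence genes 19 fell, 5 did not pass and 0 rose (20 fell adjusted over the list alone, camera adjusted p = 1.02e-13). Th1 genes (14 rose and 1 fell of 17, adjusted p = 3.97e-11, adjusted p = 0.0551 with an estimated correlation) and inhibitory receptors (10 rose and 1 fell of 12, adjusted p = 7.58e-09, adjusted p = 0.0551 with an estimated correlation) were higher by camera, with Ifng and Pdcd1 as examples. Trafficking of effector cells (14 rose and 1 fell of 16, adjusted p = 3.97e-11) and glycolysis (14 rose and 1 fell of 17, adjusted p = 1.03e-06, adjusted p = 0.293 with an estimated correlation) were higher as well, with Itgax and Hk2 as examples. Tfh genes were split (8 rose and 9 fell of 18, adjusted p = 0.861), with Pdcd1 higher and P2rx7 and Tnfsf8 lower. Cholesterol synthesis genes (10 rose and 2 fell of 20, adjusted p = 0.0453, adjusted p = 0.526 with an estimated correlation) and NK and innate-like T markers (6 rose and 1 fell of 7, adjusted p = 0.00305, adjusted p = 0.235 with an estimated correlation) were higher, with Idi1 and Klre1 as examples, and mitochondrially encoded genes were lower (0 rose and 8 fell of 13, adjusted p = 0.00127, adjusted p = 0.293 with an estimated correlation). Heat shock and dissociation stress genes did not pass as a list (5 rose and 6 fell of 15, 7 and 6 adjusted over the list alone, adjusted p = 0.974). Without the 3 libraries that stand apart, CD8 lineage genes passed as higher (6 rose and 3 fell of 10) and AP-1, NR4A and EGR genes as lower (3 rose and 8 fell of 16), each with adjusted p = 0.0489.

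Of the profiled factors in CD8 cells, Bhlhe40 rose by 8.40 ± 0.35 (564 ± 11 against 1.66 ± 0.933 CPM), Tbx21, which encodes T-bet, by 6.21 ± 0.83 (765 ± 28.6 against 10.3 ± 0.341 CPM), and Irf4 by 4.17 ± 0.20 (51.6 ± 0.952 against 2.86 ± 0.741 CPM). Jun fell by 2.83 ± 0.90 (adjusted p = 0.0299) and Ruvbl1 fell by 0.41 ± 0.09 (adjusted p = 0.0061), and Smarca4 rose by 0.33 ± 0.12 (adjusted p = 0.0448). Each of these 3 calls ended when single libraries were left out (adjusted p up to 0.155, 0.0687 and 0.232). That of Ruvbl1 also ended without the filter on low counts (adjusted p = 0.0812). Runx1, Ets1, Nfatc1, Smarca5 and Chd4 did not pass, though Chd4 passed as lower without naive CD8 replicate 1 (adjusted p = 0.0164). Nfatc1 passed with size factors in place of TMM scaling (adjusted p = 0.0211), without the filter on low counts (0.0319), with the DESeq2 Wald test (0.0121) and without the 3 libraries that stand apart (0.000126). Runx1 also passed without those 3 libraries (log2 fold change 0.58). None of the 3 is an activated or naive CD8 library, so that their absence acted mainly through the shared estimate of the spread. Calls that appear in this way are not read as hidden signals.

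**Figure D1:**
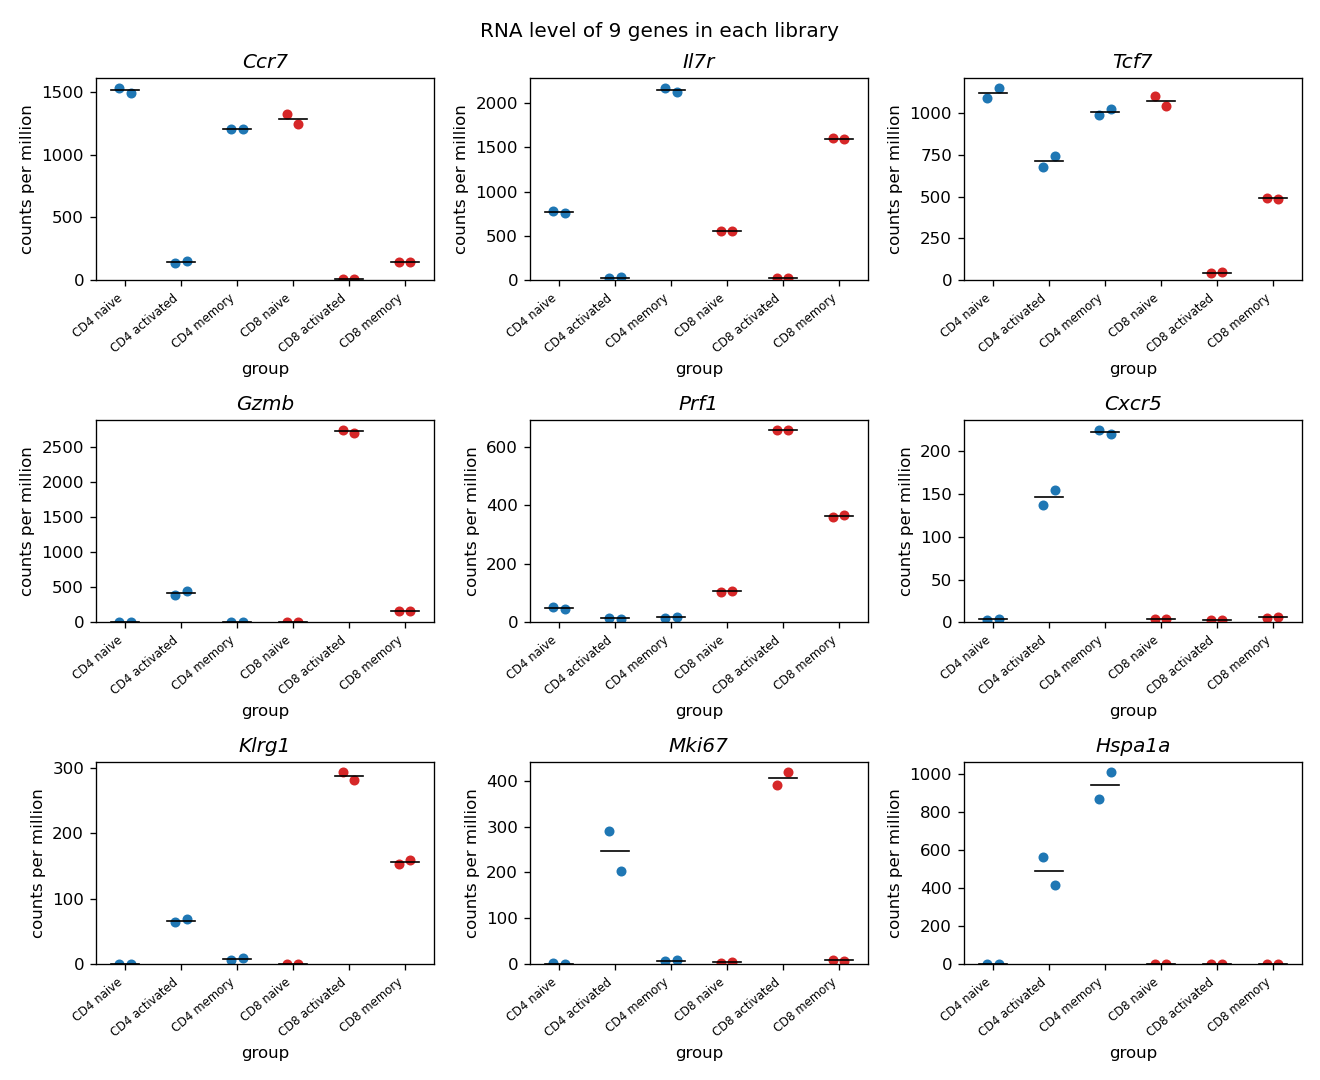
RNA level of 9 genes in each of the 12 libraries. Points are libraries and bars are means of n = 2.

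Memory CD4 cells were compared with naive CD4 cells to ask what differed at day 60. Ifng was at least 1216-fold higher (86.8 ± 1.93 CPM against 0 counts). Cxcr3 rose by 9.84 ± 0.17 (354 ± 6.64 against 0.38 ± 0.0511 CPM), and Cxcr5, which encodes the follicle homing receptor, by 6.05 ± 0.17 (222 ± 3.35 against 3.34 ± 0.48 CPM). Pdcd1 rose by 5.44 ± 0.13 (231 ± 3.47 against 5.3 ± 0.278 CPM) and Il2rb by 4.21 ± 0.11 (1017 ± 4.01 against 54.8 ± 5.6 CPM). Igfbp4 fell by 9.20 ± 0.30 (2.07 ± 0.735 against 1213 ± 27 CPM). Tcf7 did not pass (-0.16 ± 0.09, adjusted p = 0.154). Hspa1a rose by 11.44 ± 0.50 (938 ± 96.4 against 0.328 ± 0.255 CPM), and Atf3 was higher, 1001-fold (interval 179 to 39610, 1 count in the lower group). Among all genes tested, 4705 rose and 5085 fell. Lists higher by camera were Th1 (16 rose and 0 fell of 17, adjusted p = 9.65e-13, adjusted p = 0.0693 with an estimated correlation), cytotoxic effector (18 rose and 3 fell of 21, adjusted p = 1.7e-09, adjusted p = 0.113 with an estimated correlation), and Tfh (15 rose and 2 fell of 18, adjusted p = 9.35e-08, adjusted p = 0.113 with an estimated correlation), with Il12rb2, Klrk1 and Rgs16 as examples. Higher too were glycolysis (14 rose and 1 fell of 17, 14 and 2 adjusted over the list alone, adjusted p = 1.23e-07, adjusted p = 0.252 with an estimated correlation), trafficking of effector cells (14 rose and 2 fell of 16, adjusted p = 1.23e-07, adjusted p = 0.0693 with an estimated correlation) and heat shock and dissociation stress (12 rose and 2 fell of 15, adjusted p = 1.58e-06, adjusted p = 0.0653 with an estimated correlation), with Slc16a3 as an example. Inhibitory receptors (8 rose and 3 fell of 12, adjusted p = 0.0012, adjusted p = 0.252 with an estimated correlation), AP-1, NR4A and EGR genes (9 rose and 5 fell of 16, adjusted p = 0.0172, adjusted p = 0.252 with an estimated correlation) and NK and innate-like T markers (4 rose and 1 fell of 7, adjusted p = 0.0367, adjusted p = 0.254 with an estimated correlation) also passed as higher. Naive and quiescence genes (3 rose and 14 fell of 24, adjusted p = 0.000618, adjusted p = 0.113 with an estimated correlation) and interferon stimulated genes (4 rose and 18 fell of 24, adjusted p = 0.00166, adjusted p = 0.374 with an estimated correlation) were lower, with Dapl1, Ifit3 and Zbp1 as examples. Cell cycle genes did not pass as a list (15 rose and 6 fell of 35, adjusted p = 0.153).

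Memory CD8 cells were compared with naive CD8 cells in the same way. Klrg1 rose by 10.57 ± 0.51 (156 ± 4.39 against 0.0954 ± 0.135 CPM), and Zeb2, which encodes a repressor of transcription, by 10.92 ± 0.65 (198 ± 4.35 against 0.0957 ± 0.067 CPM). Klrk1 rose by 7.98 ± 0.21 (754 ± 5.33 against 2.97 ± 0.718 CPM) and Klrb1c by 4.85 ± 0.10 (326 ± 2.53 against 11.3 ± 0.0761 CPM). Ccl9 was at least 547-fold higher. Tcf7 fell by 1.13 ± 0.09 (489 ± 3.66 against 1073 ± 42 CPM). Among all genes tested, 2617 rose and 1877 fell, 4494 in sum, and fewer passed without memory CD8 replicate 2 (2748), without naive CD8 replicate 1 (2703) and without naive CD8 replicate 2 (2826). Lists higher by camera were cytotoxic effector (20 rose and 1 fell of 21, adjusted p = 1.55e-27), Th1 (14 rose and 0 fell of 17, adjusted p = 3.91e-16), and trafficking of effector cells (14 rose and 1 fell of 16, adjusted p = 1.73e-14), with Cx3cr1, Ifng and Itga1 as examples. Inhibitory receptors (8 rose and 3 fell of 12, adjusted p = 4.2e-05, adjusted p = 0.16 with an estimated correlation) and NK and innate-like T markers (3 rose and 1 fell of 7, 5 and 1 adjusted over the list alone, adjusted p = 0.00709, adjusted p = 0.219 with an estimated correlation) were also higher, with Klre1 as an example. Lower were naive and quiescence genes (1 rose and 18 fell of 24, 2 and 18 adjusted over the list alone, adjusted p = 7.69e-15) and cholesterol synthesis genes (0 rose and 12 fell of 20, 1 and 15 adjusted over the list alone, adjusted p = 4.67e-07, adjusted p = 0.118 with an estimated correlation), with Ccr9, Cyp51 and Hmgcs1 as examples. Glycolysis (10 rose and 1 fell of 17, 13 and 1 adjusted over the list alone, adjusted p = 0.00128, adjusted p = 0.432 with an estimated correlation) also passed as higher and AP-1, NR4A and EGR genes (3 rose and 5 fell of 16, 3 and 8 adjusted over the list alone, adjusted p = 0.0114, adjusted p = 0.208 with an estimated correlation) as lower. The hemoglobin genes Hba-a1 and Hbb-bs each had 78 counts against 3 in naive cells, a ratio of 25.8 (interval 8.52 to 128).

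**Figure D2:**
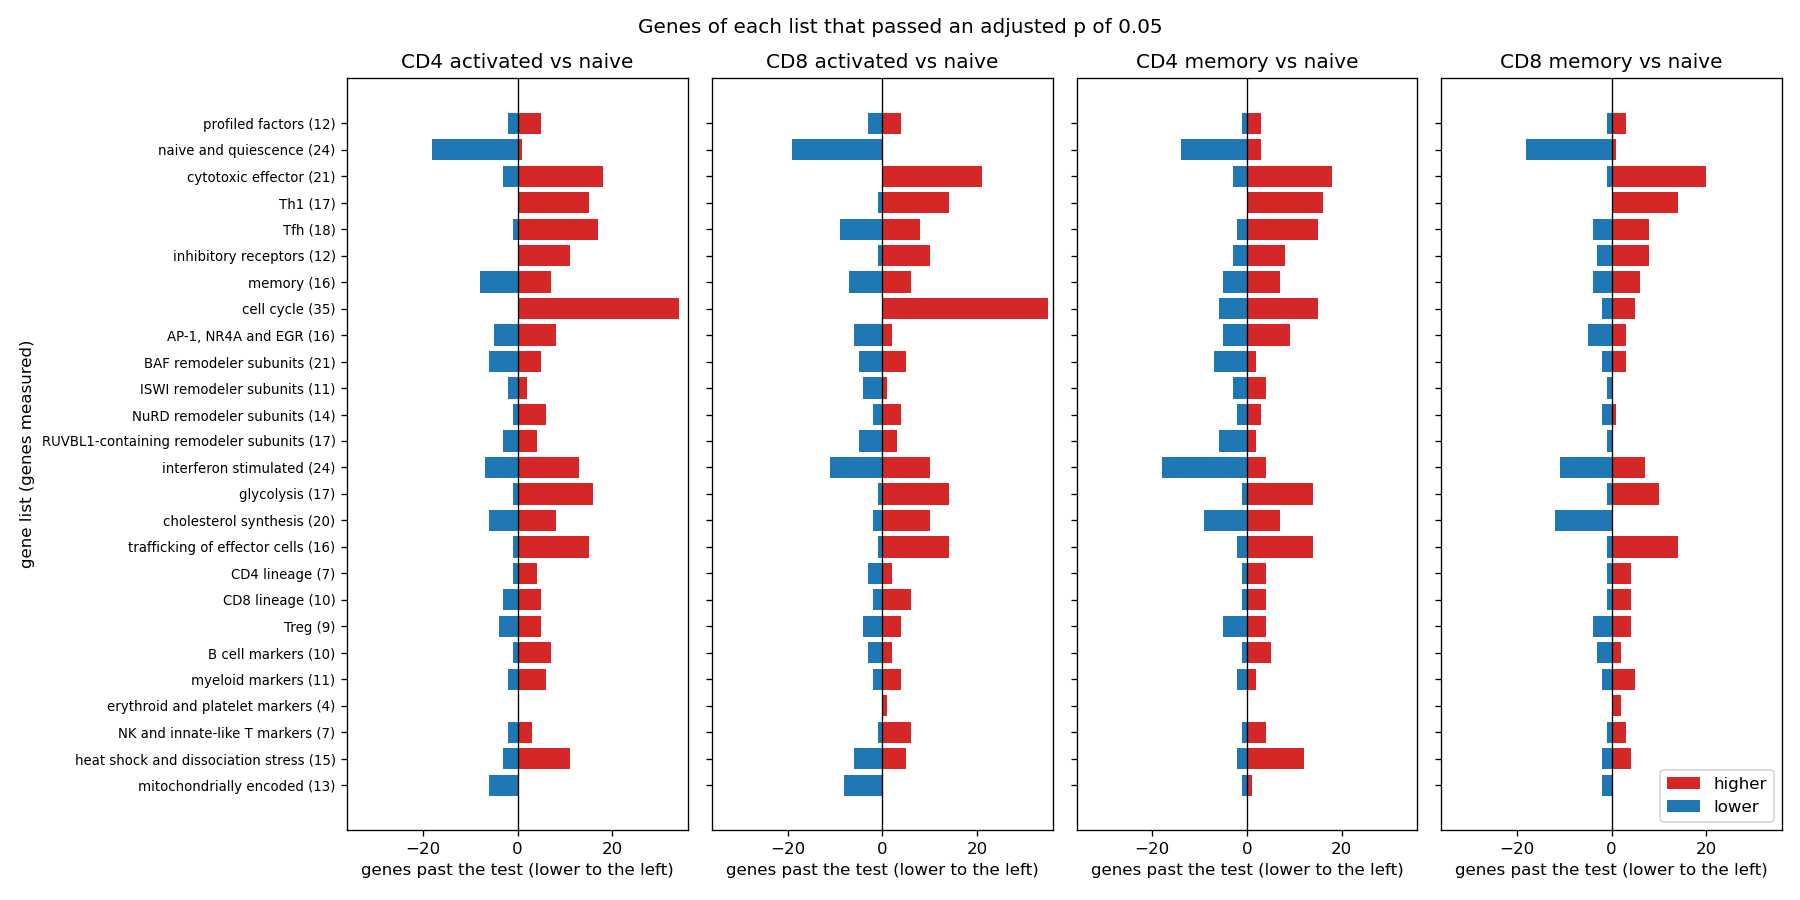
Genes of the 26 lists that were higher or lower in activated or memory cells than in naive cells, CD4 and CD8, n = 2 per group. Numbers in brackets are genes measured.

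Memory against activated CD4 cells were compared to ask what changed after day 7. Il7r, which encodes the interleukin 7 receptor, rose by 6.20 ± 0.09 (2146 ± 35.2 against 29.2 ± 3.05 CPM) and Bcl6 by 2.09 ± 0.16 (232 ± 2.35 against 54.7 ± 7.74 CPM), while Gzmb fell by 6.19 ± 0.12 (5.65 ± 0.668 against 414 ± 37.5 CPM) and Il21 fell by 2.96 ± 0.37 (8.8 ± 2.19 against 68.8 ± 6.58 CPM). Klrk1 rose by 3.85 ± 0.18 (151 ± 8.73 against 10.4 ± 1.83 CPM) and Ctla4 fell by 1.47 ± 0.08 (347 ± 8 against 960 ± 93.2 CPM). The test passed 2918 genes that rose and 4432 that fell. Among 13 lists that passed, all 35 cell cycle genes fell (adjusted p = 1.72e-28) and NK and innate-like T markers were higher (5 rose and 0 fell of 7, adjusted p = 0.00406, adjusted p = 0.282 with an estimated correlation). Camera also placed interferon stimulated genes (2 rose and 20 fell of 24, adjusted p = 1.76e-06, adjusted p = 0.282 with an estimated correlation), glycolysis (1 rose and 15 fell of 17, adjusted p = 1.7e-06, adjusted p = 0.318 with an estimated correlation) and inhibitory receptors (0 rose and 9 fell of 12, 0 and 10 adjusted over the list alone, adjusted p = 8.81e-07, adjusted p = 0.142 with an estimated correlation) lower. Naive and quiescence genes were higher (15 rose and 1 fell of 24, 16 and 2 adjusted over the list alone, adjusted p = 9.05e-06, adjusted p = 0.142 with an estimated correlation). Cytotoxic effector (4 rose and 13 fell of 21, adjusted p = 0.000461, adjusted p = 0.328 with an estimated correlation) and trafficking of effector cells (2 rose and 8 fell of 16, adjusted p = 0.00406, adjusted p = 0.282 with an estimated correlation) genes were lower. Th1 (3 rose and 9 fell of 17, 4 and 9 adjusted over the list alone, adjusted p = 0.0127, adjusted p = 0.406 with an estimated correlation) and Tfh (3 rose and 11 fell of 18, adjusted p = 0.0249, adjusted p = 0.406 with an estimated correlation) genes were lower too. AP-1, NR4A and EGR (9 rose and 2 fell of 16, adjusted p = 0.00933, adjusted p = 0.282 with an estimated correlation) and heat shock and dissociation stress (8 rose and 2 fell of 15, 10 and 2 adjusted over the list alone, adjusted p = 0.00571, adjusted p = 0.237 with an estimated correlation) genes were higher. Mitochondrially encoded (7 rose and 0 fell of 13, adjusted p = 0.00847, adjusted p = 0.406 with an estimated correlation) genes also passed as higher.

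In CD8 cells the same contrast gave lower Gzmb (-4.10 ± 0.11, 159 ± 1.06 against 2723 ± 29.5 CPM), Gzma (-3.48 ± 0.10, 32.9 ± 2.37 against 368 ± 30.3 CPM) and Eomes (-2.29 ± 0.44, 22.9 ± 9.39 against 112 ± 14.9 CPM). Nr1d1, a clock gene, rose by 7.20 ± 0.22 (51.9 ± 0.741 against 0.348 ± 0.148 CPM) and Tnfsf8 by 3.60 ± 0.10 (63.7 ± 1.69 against 5.25 ± 0.303 CPM). The test passed 4454 genes that rose and 3414 that fell, 7868 in sum, against 5176 without memory CD8 replicate 2. Without the 3 libraries that stand apart the split turned to 3635 higher and 4234 lower. Among 9 lists that passed, all 35 cell cycle genes fell (adjusted p = 1.98e-36), with Cdc6, a replication gene outside the list, at -7.01 ± 0.52. Cholesterol synthesis genes (0 rose and 17 fell of 20, 0 and 19 adjusted over the list alone, adjusted p = 2.55e-09, adjusted p = 0.115 with an estimated correlation), inhibitory receptors (2 rose and 9 fell of 12, 3 and 9 adjusted over the list alone, adjusted p = 1.34e-06, adjusted p = 0.115 with an estimated correlation) and glycolysis (2 rose and 12 fell of 17, 2 and 13 adjusted over the list alone, adjusted p = 4.85e-05, adjusted p = 0.396 with an estimated correlation) were lower. Naive and quiescence genes were higher (12 rose and 2 fell of 24, adjusted p = 0.000248, adjusted p = 0.115 with an estimated correlation). Cytotoxic effector (3 rose and 12 fell of 21, 5 and 12 adjusted over the list alone, adjusted p = 0.00353, adjusted p = 0.396 with an estimated correlation) and trafficking of effector cells (1 rose and 8 fell of 16, adjusted p = 0.0129, adjusted p = 0.396 with an estimated correlation) genes were lower. Memory (7 rose and 1 fell of 16, adjusted p = 0.00743, adjusted p = 0.396 with an estimated correlation) and mitochondrially encoded (8 rose and 0 fell of 13, adjusted p = 0.00582, adjusted p = 0.396 with an estimated correlation) genes passed as higher.

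CD8 and CD4 cells were compared within each stage, first in naive cells. Cd8a (9.72 ± 0.34, 1611 ± 16.9 against 1.9 ± 0.458 CPM), Nkg7 (8.17 ± 0.18, 309 ± 3.89 against 1.06 ± 0.325 CPM) and Itgae (7.67 ± 0.39, 221 ± 1 against 1.08 ± 0.551 CPM) were higher in naive CD8 cells. Cd4 (-9.77 ± 0.29, 1.2 ± 0.487 against 1055 ± 47.1 CPM) and Cd40lg, which encodes CD40 ligand, (-4.84 ± 0.16, 5.62 ± 0.556 against 160 ± 4.01 CPM) were lower. Zbtb7b was lower, 1182-fold (interval 404 to 5734, 3 counts in the lower group). Fasl (-5.84 ± 0.11, 0.264 ± 0.0314 against 15.5 ± 0.449 CPM) and Foxp3 (-1.70 ± 0.13, 13.6 ± 1.06 against 44.3 ± 1.71 CPM) were lower in naive CD8 cells as well. Gm44174 and Gm44175, which have no position in the gene table and whose counts were taken as uncertain, were also higher in naive CD8 cells. In naive cells 589 genes were higher and 555 lower in CD8 cells, 1144 in sum. That sum depended on single libraries, with 590 and 726 without naive CD4 replicates 1 and 2, 520 and 601 without naive CD8 replicates 1 and 2, and 2004 without the 3 libraries that stand apart. Among 12 lists that passed, CD8 lineage genes (8 higher and 0 lower of 10, adjusted p = 3.84e-25) were higher by camera, and CD4 lineage (adjusted p = 4.97e-21), Treg (adjusted p = 2.5e-17) and cholesterol synthesis genes (adjusted p = 2.61e-06, adjusted p = 0.151 with an estimated correlation) lower. B cell markers were higher (2 of 10, 3 adjusted over the list alone, adjusted p = 0.000585, adjusted p = 0.162 with an estimated correlation). Cytotoxic effector (8 higher and 2 lower of 21, 11 and 2 adjusted over the list alone, adjusted p = 6.69e-06, adjusted p = 0.162 with an estimated correlation) and Th1 (6 higher and 0 lower of 17, 11 and 1 adjusted over the list alone, adjusted p = 6.38e-12, adjusted p = 0.0503 with an estimated correlation) genes were higher too. Memory (5 higher and 2 lower of 16, 5 and 4 adjusted over the list alone, adjusted p = 0.018, adjusted p = 0.256 with an estimated correlation) and trafficking of effector cells (4 higher and 1 lower of 16, 5 and 1 adjusted over the list alone, adjusted p = 0.001, adjusted p = 0.162 with an estimated correlation) genes passed in the same direction. Cell cycle (7 higher and 0 lower of 35, 9 and 0 adjusted over the list alone, adjusted p = 0.000101, adjusted p = 0.162 with an estimated correlation) and mitochondrially encoded (0 higher and 0 lower of 13, 5 and 0 adjusted over the list alone, adjusted p = 0.00735, adjusted p = 0.314 with an estimated correlation) genes also passed as higher. Tfh (2 higher and 5 lower of 18, 3 and 6 adjusted over the list alone, adjusted p = 0.00102, adjusted p = 0.256 with an estimated correlation) genes were lower.

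Among activated cells, Prf1, which encodes perforin, was higher in CD8 cells (5.59 ± 0.12, 656 ± 1.89 against 13.7 ± 1.41 CPM). Eomes (4.43 ± 0.49, 112 ± 14.9 against 5.18 ± 3.25 CPM) and Klrk1 (4.52 ± 0.18, 241 ± 4.38 against 10.4 ± 1.83 CPM) were higher as well. Cxcr5 (-6.04 ± 0.17, 2.21 ± 0.154 against 146 ± 13.2 CPM) and Tnfsf8 (-6.51 ± 0.11, 5.25 ± 0.303 against 478 ± 50.1 CPM) were lower in CD8 cells. So were Tnfrsf4 (-8.08 ± 0.27, 1.75 ± 0.697 against 474 ± 43.8 CPM) and Ctla4 (-4.02 ± 0.09, 59.1 ± 1.25 against 960 ± 93.2 CPM). In activated cells 3066 genes were higher and 3707 lower in CD8 cells, 6773 in sum, against 4428 without activated CD8 replicate 2. All 18 Tfh genes were lower (adjusted p = 3.72e-18), as were 16 of 17 glycolysis genes (adjusted p = 8.59e-12, adjusted p = 0.101 with an estimated correlation). Lower as well were 13 of 15 heat shock and dissociation stress genes (adjusted p = 9.17e-08) and 10 of 16 AP-1, NR4A and EGR genes (adjusted p = 1.54e-05). Of 35 cell cycle genes 24 were higher and 0 lower (28 adjusted over the list alone, camera adjusted p = 4.99e-11), and of 21 cytotoxic effector genes 18 were higher and 3 lower (adjusted p = 2.59e-14). Markers of other cells moved as well, with NK and innate-like T markers higher (6 of 7, adjusted p = 2.86e-05). B cell markers were lower (5 of 10, 6 adjusted over the list alone, 1 higher, adjusted p = 0.0034, adjusted p = 0.167 with an estimated correlation). Trafficking of effector cells genes were higher (12 of 16, 2 lower, adjusted p = 3.22e-05, adjusted p = 0.0562 with an estimated correlation). So were CD8 lineage genes (adjusted p = 4.99e-11). Lower were naive and quiescence genes (13 of 24, 1 higher, 14 and 4 adjusted over the list alone, adjusted p = 8.96e-05). CD4 lineage (adjusted p = 1.63e-10) and Treg genes (adjusted p = 0.000128, adjusted p = 0.101 with an estimated correlation) were lower too.

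Among memory cells, Gzmb (4.82 ± 0.12, 159 ± 1.06 against 5.65 ± 0.668 CPM), Prf1 (4.44 ± 0.11, 362 ± 3.86 against 16.7 ± 1.86 CPM) and Crtam (3.83 ± 0.10, 135 ± 5.87 against 9.48 ± 0.645 CPM) were higher in CD8 cells. Rgs16 (-6.40 ± 0.34, 2.96 ± 0.472 against 251 ± 9.42 CPM), Cxcr5 (-5.22 ± 0.16, 5.95 ± 0.911 against 222 ± 3.35 CPM) and Ctla4 (-4.97 ± 0.09, 11 ± 0.353 against 347 ± 8 CPM) were lower. In memory cells 4850 genes were higher and 3185 lower in CD8 cells. Of 12 lists that passed, lower ones were Tfh (16 of 18, 17 adjusted over the list alone, adjusted p = 2.43e-12), AP-1, NR4A and EGR (12 of 16, adjusted p = 2.4e-09), heat shock and dissociation stress (12 of 15, adjusted p = 1.69e-09), glycolysis (14 lower and 3 higher, adjusted p = 2.32e-07, adjusted p = 0.243 with an estimated correlation) and cholesterol synthesis (12 lower and 5 higher, adjusted p = 0.00146, adjusted p = 0.243 with an estimated correlation). Cytotoxic effector genes were higher (18 of 21, adjusted p = 7.27e-12, adjusted p = 0.0663 with an estimated correlation). Interferon stimulated genes were higher as well (14 of 24, adjusted p = 0.0119, adjusted p = 0.483 with an estimated correlation). Trafficking of effector cells (11 higher and 1 lower of 16, adjusted p = 7.05e-05, adjusted p = 0.0942 with an estimated correlation) and CD8 lineage (8 higher and 0 lower of 10, adjusted p = 6.09e-07) genes were higher. Naive and quiescence (2 higher and 14 lower of 24, adjusted p = 0.000267, adjusted p = 0.0761 with an estimated correlation) and CD4 lineage (0 higher and 6 lower of 7, adjusted p = 2.32e-07) genes were lower. Treg (1 higher and 7 lower of 9, adjusted p = 0.00078, adjusted p = 0.152 with an estimated correlation) genes were lower too.

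Whether the change from naive to activated cells differed between lineages was tested with the interaction, the CD8 change minus the CD4 change. Fasl changed by 6.29 ± 0.13 more in CD8 cells, where it rose from 0.264 to 119 CPM, and Klrk1 by 2.93 ± 0.26. Cxcr5 (-6.14 ± 0.22), Tnfsf8 (-6.16 ± 0.14), Nkg7 (-6.40 ± 0.21), Itgae (-7.28 ± 0.48), Cd83 (-9.40 ± 0.45) and Ikzf2 (-3.68 ± 0.17) rose less or fell more in CD8 cells. Zbtb7b, which encodes the CD4 lineage factor ThPOK, fell in CD4 cells by 0.56 ± 0.14 and was higher in activated than in naive CD8 cells, 253-fold (interval 86.4 to 1231, 3 counts in the lower group), and this difference passed the interaction test (adjusted p = 7.76e-07). Of 4022 genes that passed, 1678 differed upward and 2344 downward. Among 12 lists that passed, the interaction was negative for Tfh (15 of 18 genes, adjusted p = 9.41e-14, adjusted p = 0.1 with an estimated correlation), glycolysis (15 of 17, adjusted p = 3.51e-12, adjusted p = 0.126 with an estimated correlation), heat shock and dissociation stress (12 of 15, adjusted p = 1.51e-08) and Th1 genes (9 of 17, adjusted p = 5.8e-07, adjusted p = 0.125 with an estimated correlation). It was negative for B cell markers as well (7 of 10, adjusted p = 8.95e-05, adjusted p = 0.126 with an estimated correlation). The interaction was positive for cytotoxic effector (9 upward and 4 downward of 21, 11 and 4 adjusted over the list alone, adjusted p = 0.000365, adjusted p = 0.254 with an estimated correlation) and cell cycle (8 upward and 1 downward of 35, 11 and 1 adjusted over the list alone, adjusted p = 0.000639, adjusted p = 0.19 with an estimated correlation) genes. Positive as well were cholesterol synthesis (6 upward and 2 downward of 20, 10 and 2 adjusted over the list alone, adjusted p = 0.00224, adjusted p = 0.254 with an estimated correlation) genes. Naive and quiescence (2 upward and 12 downward of 24, 3 and 13 adjusted over the list alone, adjusted p = 0.000345, adjusted p = 0.125 with an estimated correlation) and memory (2 upward and 9 downward of 16, 2 and 10 adjusted over the list alone, adjusted p = 3.09e-05, adjusted p = 0.125 with an estimated correlation) genes were negative. AP-1, NR4A and EGR (0 upward and 8 downward of 16, 0 and 10 adjusted over the list alone, adjusted p = 3.09e-05, adjusted p = 0.125 with an estimated correlation) and CD4 lineage (2 upward and 4 downward of 7, adjusted p = 0.0271, adjusted p = 0.254 with an estimated correlation) genes were negative too.

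ATAC-seq asked where chromatin accessibility differed, with 50807 peaks tested in each of 10 comparisons. Within 50 kb of Ifng, 19 of 20 peaks opened in activated CD4 cells and 17 of 20 in activated CD8 cells, and at Tbx21 19 of 21 opened in each lineage. Around Prf1, 10 of 13 peaks gained accessibility in CD8 cells (1 lost it), whereas in CD4 cells 1 gained and 6 lost it. At Il7r, 8 of 10 peaks lost accessibility in CD4 cells and all 10 in CD8 cells, and at Lef1 22 and 24 of 35 lost it. Gains and losses past the test numbered 16197 and 15519 in activated against naive CD4 cells and 16680 and 17905 in CD8 cells. A peak in Atp10b (chromosome 11 from 43174346 to 43175126, GRCm38) was at least 177-fold higher in activated CD4 cells, and a peak in Ntrk2 (chromosome 13 from 59025326 to 59026149) was at least 164-fold lower in activated CD8 cells. Floors and intervals of peaks make no allowance for counts that come in pairs.

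In memory cells, accessibility was again compared with naive cells and with activated cells. Against naive cells 16024 peaks gained and 14265 lost accessibility in CD4 cells and 12559 and 11439 in CD8 cells, including gains at 18 of 20 Ifng peaks in CD4 cells and 9 of 13 Prf1 peaks in CD8 cells. Against activated cells, Il7r regained accessibility at 8 of 10 peaks in CD4 cells and at all 10 in CD8 cells, Tbx21 lost it at 19 and 16 of 21 peaks, and Tcf7 gained it at 14 of 20 peaks in CD8 cells. A peak inside Bach2 (chromosome 4 from 32560167 to 32560989) was higher in memory than in activated CD8 cells, 202-fold (interval 35.7 to 8028, 1 count in the lower group). Memory against activated cells gave 11558 higher and 11191 lower peaks in CD4 cells and 14258 and 11255 in CD8 cells.

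Between lineages, a peak 3502 bp from Cd8a (chromosome 6 from 71369254 to 71369924) was higher in naive CD8 cells by 7.31 ± 0.30 (30.6 ± 2.84 against 0.19 ± 0.109 CPM), and a peak inside Zbtb7b (chromosome 3 from 89382001 to 89382536) was lower (-4.55 ± 0.31, 0.871 ± 0.387 against 19.9 ± 0.182 CPM). All 17 peaks around Cd8a were higher in activated CD8 cells, 12 of 13 around Prf1 and 7 of 8 around Gzmb, while 8 of 13 around Cxcr5 and 12 of 20 around Tcf7 were lower. In naive cells 9413 peaks were higher and 7849 lower in CD8 cells, 17262 in sum, against 11218 without naive CD8 replicate 2, and with total counts as the scale the split turned to 7170 higher and 10741 lower. Activated cells gave 9985 higher and 12537 lower and memory cells 10292 and 10165. The interaction passed at 17081 peaks, 6414 upward and 10667 downward (8356 and 8969 with total counts as the scale), with 12 of 13 Prf1 peaks upward and 8 of 13 Cxcr5 and 10 of 20 Tcf7 peaks downward. Genes are named by position alone.

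CUT&RUN of Runx1 asked where binding differed, with 34661 peaks tested in 4 comparisons. Binding rose at 18 of 18 peaks around Tbx21 in activated CD4 cells and at 17 of 18 in CD8 cells, and fell at 22 of 27 and 21 of 27 peaks around Lef1. Around Prf1, binding rose at 10 of 12 peaks in activated CD8 cells, and in activated cells all 12 were higher in CD8 than in CD4 cells. A peak in Cdh17 (chromosome 4 from 11768834 to 11769695) was at least 698-fold higher in activated CD8 cells. A peak 15163 bp from Cd8a (chromosome 6 from 71356987 to 71358263) was higher in activated CD8 than CD4 cells by 8.05 ± 0.37 (46.3 ± 2.62 against 0.16 ± 0.226 CPM). Rises and falls numbered 12927 and 11137 in CD4 cells (10452 and 4982, 15434 in sum, with the satellite region as the scale) and 12782 and 11718 in CD8 cells. With that scale the CD8 split turned to 7634 and 9005. CD8 against CD4 activated cells gave 7651 higher and 7372 lower peaks. The interaction passed at 8554 peaks, 3701 upward and 4853 downward, or 2884 and 6071 with total counts as the scale.

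Binding of Tcf1 was compared over 24772 peaks. Activated CD8 libraries held 1.02 M and 1.04 M counts in peaks, against 5.49 M and 7.48 M in naive CD8 libraries. Of these counts 11.5% against 1.07% lay in peaks within 10 kb of the satellite region. TMM scaling sets the typical peak near no change, so that rises and falls are relative to the other Tcf1 peaks. On that scale binding around Ifng rose at 9 of 13 peaks in activated CD4 cells and at 7 of 13 in CD8 cells. Around Lef1 it fell at 13 of 19 and 10 of 19. All 15 peaks around Cd8a were higher in activated CD8 than in CD4 cells. A peak 2377 bp from Gzmk (chromosome 13 from 113183343 to 113183645) was at least 168-fold higher in activated than in naive CD8 cells. In CD4 cells 4798 peaks rose and 4058 fell, 8856 in sum, against 5714 and 5703 without naive CD4 replicates 1 and 2. In CD8 cells 3391 rose and 3645 fell, 7036 in sum, against 4489 without activated CD8 replicate 2, 4270 without naive CD8 replicate 1 and 4186 without naive CD8 replicate 2. With this region as the scale, chosen after the data were seen, 16156 of 17655 calls in CD4 cells and 23434 of 23748 in CD8 cells were falls.

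Activated CD8 against CD4 cells gave 1242 higher and 2416 lower Tcf1 peaks, 3658 in sum. Left-out libraries moved this sum to 6013 (activated CD4 replicate 2), 1956 (activated CD8 replicate 1) and 2090 (activated CD8 replicate 2). The interaction for Tcf1 passed at 1275 peaks, 434 upward and 841 downward, and at 3 of 5 Prf1 peaks it was upward. Its sum moved to 2867 without activated CD4 replicate 2, to 348 and 320 without naive CD4 replicates 1 and 2, to 431 and 704 without activated CD8 replicates 1 and 2, and to 429 and 402 without naive CD8 replicates 1 and 2.

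Binding of Ets1 was compared over 14897 peaks. Counts fell most at a peak on chromosome 1 from 24612303 to 24613729, 24380 bp from Col19a1. They fell in CD4 cells (-5.34 ± 0.30, 10.4 ± 5.2 against 448 ± 20.3 CPM) and in CD8 cells (-5.96 ± 0.31, 8.99 ± 2.73 against 558 ± 174 CPM). Whether counts at this peak reflect binding of Ets1 was not tested. Binding rose at 3 of 5 Tbx21 peaks in each lineage and fell at 9 of 18 Lef1 peaks in CD8 cells. In CD4 cells 1923 peaks rose and 1425 fell, 3348 in sum, against 2169 and 1422 without naive CD4 replicates 1 and 2, and the split was 372 and 2158 with the satellite region as the scale. In CD8 cells 1709 rose and 1542 fell, 3251 in sum, against 1839 and 2103 without activated CD8 replicates 1 and 2 and 1810 and 1817 without naive CD8 replicates 1 and 2. That split was 1436 and 2075 with total counts as the scale and 269 and 12865, 13134 in sum, with the satellite region.

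Between lineages, Ets1 binding differed at 201 peaks in activated cells, 89 higher and 112 lower in CD8 cells, with 5 of 11 peaks around Cd8a higher. That count was 115 with the DESeq2 Wald test, 562 without activated CD4 replicate 1, and 38 and 18 without activated CD8 replicates 1 and 2. The interaction for Ets1 passed at 79 peaks (16 upward, 63 downward), at 31 with the DESeq2 Wald test and at 957 without activated CD4 replicate 1. It passed at 11 and 21 peaks without naive CD4 replicates 1 and 2, at 11 and 17 without activated CD8 replicates 1 and 2, and at 11 and 3 without naive CD8 replicates 1 and 2.

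The other 9 antibodies were compared between activated CD8 and CD4 cells, 1 comparison each. At the Prf1 locus each peak of Chd4 (11), Snf2h (12), Rvb1 (9), Jun (6), Bhlhe40 (6), Brg1 (5), Irf4 (4), T-bet (3) and Nfatc1 (2) was higher in CD8 cells. Peaks around Cd8a were higher as well, at 13 of 13 for Chd4, 14 of 14 for Snf2h and 11 of 11 for Irf4, and none of the 11 Brg1 peaks around Ifng passed. Cxcr5 peaks were lower in CD8 cells at 7 of 11 for Chd4 and 5 of 7 for Irf4. For Snf2h a peak 2857 bp from Cd8a (chromosome 6 from 71368513 to 71370569) was higher by 5.93 ± 0.30 (36.2 ± 1.03 against 0.645 ± 0.223 CPM), and for Chd4 a peak 584 bp from Rmnd5a (chromosome 6 from 71387141 to 71388049) by 6.96 ± 0.39 (31.3 ± 2.65 against 0.238 ± 0.0411 CPM). A Bhlhe40 peak inside Stim1 (chromosome 7 from 102322087 to 102322806) was lower in CD8 cells, 80.7-fold (interval 27 to 396, 3 counts in the lower group), and a T-bet peak inside Zdhhc14 (chromosome 17 from 5567831 to 5568350) was at least 19.9-fold higher.

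**Figure D3:**
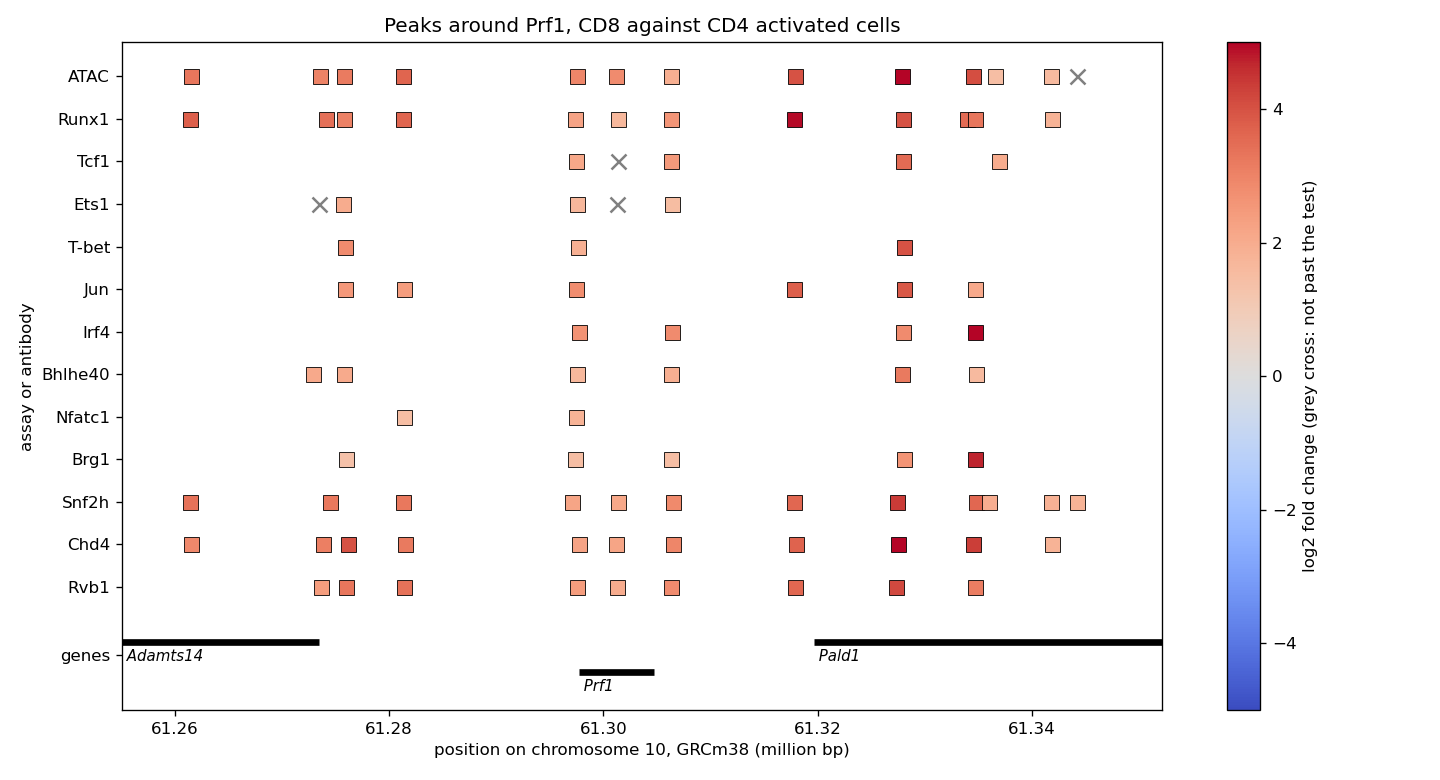
Peaks within 50 kb of Prf1 in ATAC-seq and CUT&RUN, activated CD8 against CD4 cells, n = 2 per group. Colour gives the log2 fold change and crosses mark peaks that did not pass.

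Counts for these 9 antibodies were as follows, higher and lower in CD8 cells. Snf2h gave 5872 and 4337 of 31186 peaks, Chd4 3888 and 3793 of 25568, and Rvb1 4675 and 3860 of 24197, the last with 8535 in sum against 5346 without activated CD8 replicate 1. Jun gave 2412 and 2180 of 13255 (4592 in sum, 2394 with the DESeq2 Wald test), and Irf4 gave 1224 and 1221 of 9526 (2445 in sum, 847 with that test, 793 and 1159 without activated CD4 replicates 1 and 2). T-bet gave 1190 and 623 of 7118, or 1066 and 303 with total counts as the scale. Its sum of 1813 fell to 659 with the DESeq2 Wald test, to 1179 without activated CD4 replicate 1, and to 1023 and 661 without activated CD8 replicates 1 and 2. Bhlhe40 gave 861 and 864 of 11280, or 1199 and 617 with total counts as the scale, and its sum of 1725 fell to 822 with the DESeq2 Wald test and to 32 and 39 without activated CD8 replicates 1 and 2. Nfatc1 gave 778 and 881 of 5349, and 1659 in sum became 579 with the DESeq2 Wald test and 585 and 612 without activated CD8 replicates 1 and 2. Brg1 gave 599 and 659 of 14054, or 685 and 463 with total counts as the scale, and 1258 in sum became 311 with the DESeq2 Wald test and 342 and 484 without activated CD8 replicates 1 and 2.

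Binding was then set against accessibility. Peaks of all 12 antibodies overlapped ATAC-seq peaks by at least 1 bp at 100%. How the peak lists were made is not given, so this share is not read as a measure of targeting. Of ATAC-seq peaks, 66.2% overlapped a Runx1 peak, 68.2% a Snf2h peak, 48.1% a Tcf1 peak, 14.6% a T-bet peak and 10.2% an Nfatc1 peak. Of peaks that lost accessibility in activated CD4 cells, 63.8% were bound by Tcf1, against 42.8% of peaks that gained it. Odds ratios by Fisher's exact test set gained or lost peaks against all other peaks tested, lost or gained ones included. Among the 3 antibodies with naive and activated libraries, odds ratios at gained peaks were highest for Runx1 (2.73 in CD4 and 3.26 in CD8 cells). At lost peaks they were highest for Tcf1 (2.35 and 2.53). Tcf1 libraries held more counts in peaks in naive CD4 cells (7.36 M and 6.06 M) than in activated ones (4.03 M and 1.99 M). CD8 values are above. Runx1 had more in activated CD4 cells (11.55 M and 11.95 M) than in naive ones (8.27 M and 8.9 M). Whether this balance shaped the 2 peak lists, and with them these odds ratios, was not tested. The other 9 antibodies were profiled in activated cells alone, so that sites that had closed were not assayed while open. Their odds ratios were 1.83 to 4.82 at gained peaks and 0.3 to 0.78 at lost peaks, as this design alone would favour. They are not ranked against the 3 above. Against unchanged peaks alone, each of the 9 bound a smaller share of lost peaks in CD4 cells. In CD8 cells the share was larger for T-bet (12.9% against 10.8%), Irf4 (16% against 14.8%), Bhlhe40 (18.1% against 16.7%) and Brg1 (21.4% against 20.9%). Nfatc1 gave 6.6% for both. Shares were smaller for Jun (18.2% against 18.4%), Chd4 (45.8% against 46.9%), Rvb1 (41.8% against 42.7%) and Snf2h (56.2% against 65.9%). Of 48 such tests with Benjamini-Hochberg adjustment, 47 passed, and Ets1 at gained peaks of CD8 cells did not (odds ratio 1.03, adjusted p = 0.203). Ets1 bound 29.1% of those gained peaks, 24.5% of unchanged and 32.2% of lost ones. In CD4 cells it bound 24.9% of gained and 30.1% of unchanged peaks. Runx1 at lost peaks had odds ratios of 0.89 (CD4) and 0.95 (CD8). Its shares there (66% and 67%) were above those of unchanged peaks (57.7% and 52.7%). Peaks overlapped by none had fewer counts and changed less often (below), and odds ratios and shares were not adjusted for this. Peaks are not independent replicates.

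Changes of binding and of accessibility at overlapping peaks were correlated, without a p value because peaks are not independent replicates. For Runx1 the correlation was 0.89 in CD4 and 0.88 in CD8 cells (activated against naive), for Tcf1 0.85 and 0.64 and for Ets1 0.66 and 0.69. In activated CD8 against CD4 cells it was 0.89 for Chd4, 0.86 for Rvb1, 0.84 for Snf2h, 0.82 for Runx1, 0.52 for Tcf1 and 0.51 for Nfatc1. ATAC-seq peaks overlapped by 11 to 12 antibodies (3784 peaks) had a median of 52.7 CPM, and 67.3% of them changed in activated CD4 cells. Peaks overlapped by none (7754) had a median of 2.17 CPM, and 48.3% changed. The median size of the log2 fold change went the other way, 0.31 against 0.91 in CD4 cells and 0.44 against 1.06 in CD8 cells. Neither measure was adjusted for the difference in counts. RNA changes of 11685 genes correlated with the mean ATAC-seq change within 1000 bp of the gene span at 0.48 in activated CD4 cells, 0.49 in activated CD8 cells, 0.42 and 0.47 in memory CD4 and CD8 cells and 0.43 between lineages in activated cells.

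Activated and memory cells were compared with the same naive libraries, and the calls they shared were counted. In CD4 cells 2896 genes rose in both and 3088 fell in both, against 1243 and 1228 for independent calls, with 740 in opposite directions. In CD8 cells 1807 rose and 1386 fell in both, against 600 and 448, with 305 opposite. ATAC-seq gave 11631 and 9191 shared peaks in CD4 cells against 5108 and 4357, and 10415 and 9553 in CD8 cells against 4123 and 4031. Changes correlated at 0.79 (covariance 2.6) and 0.6 (1.74) for RNA of CD4 and CD8 cells and at 0.87 (2.34) and 0.86 (2.5) for ATAC-seq. Simulations without any change, with shared naive libraries, gave 0 shared calls, correlations of 0.49, 0.5, 0.44 and 0.51 and covariances of 0.081, 0.082, 0.033 and 0.042 in that order. Each simulated covariance was below the observed one. The simulations did not hold the deviation shared by libraries of activated and memory CD4 RNA given below. Naive groups of n = 2 were not split, since each part would hold 1 library. Part of the excess in shared calls may come from the shared controls.

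In 3 RNA libraries, replicate 2 of activated CD4, replicate 1 of memory CD4 and replicate 2 of memory CD8 cells, Jund and Socs1 were low against the other replicate. Jund stood at 15.2 against 228 CPM in activated CD4 cells, 24.6 against 161 CPM in memory CD4 cells and 8.87 against 77.9 CPM in memory CD8 cells. Socs1 stood at 1.47 against 16.9, 3.98 against 19.2 and 7.17 against 38.6 CPM. Gm10800, a member of a satellite family with near-identical copies and an uncertain count, was higher in the same 3 libraries (359 against 192, 674 against 508 and 524 against 209 CPM). Replicate differences correlated across 6226 genes at 0.94 to 0.97 between these 3 pairs. Genes are not independent replicates. Differences of the other 3 pairs (replicate 2 minus replicate 1) correlated with them at 0.41 to 0.44 in naive CD8, -0.47 to -0.44 in activated CD8 and -0.39 to -0.34 in naive CD4 cells. Where the sign is negative, replicate 1 had less Jund RNA, so each pair shared the direction in part. Tbx21 (63.4 against 225 CPM), Jun (18 against 95.6 CPM) and Ets1 (1490 against 4150 CPM) were lower in replicate 2 than in replicate 1 of activated CD4 cells as well. Hspa1a was high in both libraries of activated CD4 (566 and 416 CPM) and memory CD4 cells (869 and 1010 CPM) and at most 2.33 CPM in each other library.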

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

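Tests of a single odd library for the heat shock transcripts were chosen after the result was seen, and that of the cells sorted for RNA before. Results stand here because the change from naive to activated cells differed between CD8 and CD4 cells in the interaction test of edgeR's quasi-likelihood model. It differed for 4022 genes, 17081 ATAC-seq peaks, 8554 Runx1 peaks, 1275 Tcf1 peaks and 79 Ets1 peaks. The CD8 change minus the CD4 change, on the log2 scale, was positive for Fasl (6.29), Itgax (5.25), Itgam (4.60), Itga1 (3.02), Klrk1 (2.93), Trdc (2.92), Klre1 (2.78), Foxp3 (2.11) and Pdcd1 (1.31). It was also positive for Lss (1.08), Irf4 (0.84), Idi1 (0.62) and Il7r (0.42). It was negative for Cd83 (-9.40), Hspa1a (-8.93), Itgae (-7.28), Hspa1b (-7.15), Nkg7 (-6.40), Cxcr6 (-6.39), Tnfsf8 (-6.16), Cxcr5 (-6.14) and Tnfrsf4 (-5.35). It was also negative for Cd22 (-5.32), P2rx7 (-4.72), Cxcr3 (-4.60), Il21 (-4.53), Gadd45b (-4.23), Hk2 (-4.18), Ccr7 (-4.17), Tcf7 (-3.92) and Ikzf2 (-3.68). Smaller ones were found for Rgs16 (-3.59), Slc16a3 (-3.48), Dapl1 (-2.86), Tpi1 (-2.81), Batf (-2.17), Cd40lg (-2.05), Ctla4 (-1.92), Cdk1 (-1.85) and Ighm (-1.57). Further ones were found for Lyz2 (-1.13), Ss18 (-0.70), Chd4 (-0.68) and Mbd2 (-0.52). Genes with at most 3 counts in a group had no fitted size, and the test gave adjusted p = 0.00902 for Ifng, 7.76e-07 for Zbtb7b, 0.0181 for Tppp3, 0.0387 for Gzmk, 0.0127 for Nfam1 and 0.00456 for Cx3cr1.

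Peaks with the largest such differences are named by the nearest gene, by position alone. For ATAC-seq, peaks near Trak1 (chromosome 9 from 121305466 to 121306250, 9.23 and 12.4 CPM in the 2 activated CD8 libraries, 0 in naive CD8 cells, adjusted p = 1.47e-05) and Zdhhc14 (chromosome 17 from 5567706 to 5568349, 20.7 and 21.6 CPM, adjusted p = 1e-05) were higher in CD8 cells after activation. Peaks near Hdac4 (chromosome 1 from 91942630 to 91943040, 7.32 and 5.12 CPM in activated CD4 cells, adjusted p = 1.26e-05) and Tfap2a (chromosome 13 from 40676516 to 40677227, 10.8 and 12.8 CPM, adjusted p = 0.000103) were higher in CD4 cells. For Runx1, peaks near Rtn4ip1 (chromosome 10 from 43934615 to 43935155, 19.6 and 19.4 CPM in activated CD8 cells, adjusted p = 0.00134) and Gzmk (chromosome 13 from 113180805 to 113181161, 15.4 and 13.2 CPM, adjusted p = 0.00572) stood against peaks near Ipmk (chromosome 10 from 71363489 to 71364256, 16.3 and 24.2 CPM in activated CD4 cells, adjusted p = 0.0337) and Prickle1 (chromosome 15 from 93514051 to 93514338, 9.77 and 8.32 CPM, adjusted p = 1e-04). For Tcf1, peaks near Zfp677 (chromosome 17 from 21356049 to 21356384, 20.1 and 12.8 CPM in naive CD4 cells, adjusted p = 0.0161) and Khdrbs3 (chromosome 15 from 68944018 to 68944322, 9.05 and 12.5 CPM, adjusted p = 0.00235) were lost in CD4 cells, and a peak near Ago2 (chromosome 15 from 73110329 to 73110590, 18.3 and 23.2 CPM in activated CD4 cells, adjusted p = 0.0296) was gained there. For Ets1, a peak near Sh2d2a (chromosome 3 from 87840985 to 87841174) had adjusted p = 0.0233 (23.4 and 15.5 CPM in activated CD8 cells), and peaks near Lrrc8c (chromosome 5 from 105609618 to 105610069, 4.72) and Tomm20 (chromosome 8 from 126826276 to 126826700, -4.67) had fitted differences. Each of the Tcf1 and Ets1 peaks, and the Runx1 peaks near Gzmk and Ipmk, lost its call when some single library was left out.

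Hspa1a, a heat shock transcript, was high in activated and memory CD4 RNA alone. It stood at or above 100 CPM in all 4 of these libraries, which excludes a single odd library as the source. If cells sorted for RNA had been stressed apart from those sorted for ATAC-seq, ATAC-seq peaks near the 15 genes of the list would show little difference. Their median log2 fold change in activated CD8 against CD4 cells was -0.06 over 20 peaks, with 2 higher and 7 lower. In memory cells it was 0.32, with 10 higher and 2 lower, and in memory against naive CD4 cells -0.26, with 3 higher and 13 lower, both opposite to the RNA of the list. In activated against naive CD4 cells it was 0.19, with 10 higher and 5 lower, and for the interaction -0.25, with 0 upward and 7 downward, both in the direction of the RNA. Peaks thus differed between lineages, but not in the direction of the RNA at both stages, which leaves this explanation open. No test separated a difference of the CD4 cells themselves from a difference in their handling.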

How the results depend on the processing

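Of 41 counts of genes or peaks that passed, 19 had a left-out library that moved them beyond 1.5 times, and leaving a library out also leaves a group with n = 1. The ranges over left-out libraries were, for RNA, 2703 to 3352 (CD8 memory against naive), 5176 to 6719 (CD8 memory against activated), 520 to 726 and 4428 to 6652 (CD8 against CD4, naive and activated). For ATAC-seq of naive CD8 against CD4 cells the range was 11218 to 14497. For Tcf1 it was 5703 to 10147 (CD4), 4186 to 5084 (CD8), 1956 to 6013 (CD8 against CD4) and 320 to 2867 (interaction), and for Ets1 in that order 1422 to 4387, 1810 to 2103, 18 to 562 and 3 to 957. For the others, CD8 against CD4 activated cells, it was 661 to 1487 (T-bet), 793 to 2097 (Irf4), 32 to 2016 (Bhlhe40), 585 to 1496 (Nfatc1), 342 to 1298 (Brg1) and 5346 to 9804 (Rvb1). The DESeq2 Wald test lowered the counts to 115 (Ets1, CD8 against CD4), 31 (Ets1 interaction), 659 (T-bet), 2394 (Jun), 847 (Irf4), 822 (Bhlhe40), 579 (Nfatc1) and 311 (Brg1). The cause was not tested. With the satellite region as the scale, chosen after the data were seen, counts were 15434 (Runx1, CD4), 17655 and 23748 (Tcf1, CD4 and CD8) and 13134 (Ets1, CD8). Without the 3 RNA libraries that stand apart, also chosen after the data were seen, 2004 genes differed between naive lineages. Of list calls 20 appeared and 1 ended without them, with profiled factors in 5 comparisons and CD8 lineage in 4 among those that appeared. Leaving these libraries out by itself favours more calls, as described above. Of 260 list tests 112 passed at the preset correlation and 30 with an estimated correlation. The labels did not say that replicate numbers pair libraries. Differences between same-numbered libraries correlated at -0.78 to 0.82 for RNA, at most 0.03 for ATAC-seq, -0.02 to 0.32 for Runx1, 0.02 to 0.19 for Tcf1 and -0.11 to 0.06 for Ets1. With 1 pair of groups each they correlated at 0.33 (Chd4), 0.29 (Snf2h), 0.25 (Rvb1) and 0.13 (Brg1), and between -0.04 and 0.01 for the other 5 antibodies, too few pairs to show pairing. With the replicate number as a block the Ets1 interaction passed at 154 peaks and 40 counts stayed within 1.5 times, among them Chd4 with 11151 and Snf2h with 13267. Under the block the adjusted p in activated against naive cells was 0.0554 for Jun and 0.0514 for Smarca4 in CD4 cells and 0.0656 for Smarca4 in CD8 cells. Size factors (42 results), no filter (45) and total counts in peaks (31) left each count within 1.5 times, and splits that total counts moved stand beside their counts. Named genes and peaks were followed over all alternatives together, with left-out libraries among them. Of these results 6010 kept their direction and stayed on the same side of the threshold. A further 205 calls ended, 20 appeared, and 23 results that had not passed changed direction. The majority of rises or falls turned under at least 1 alternative for 27 of the 41 counts, so that near-even splits show no direction. Counts in peaks, which are not depth, were lowest for T-bet (0.24 M at least) and Nfatc1 (0.25 M). Motif and promoter windows were not run, as stated above.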

Other observations

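Tests of DNA as the whole cause, of gene span length, of background and of Tcf1 level were chosen after the results were seen, and the test of DNA as a part before. Beyond the comparisons above, Zbtb7b, which encodes the CD4 lineage factor ThPOK, gained accessibility at 8 of 12 peaks within 50 kb in activated CD8 cells, and lost it at 10 of 12 in memory CD4 cells. At the Bcl6 locus 5 of 8 peaks were more accessible in memory than in activated CD4 cells, and at Runx3 15 of 27 were less so.

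In activated CD4, memory CD4 and memory CD8 RNA, one library of each pair differed from the other in the same genes, and the differences correlated at 0.95, 0.97 and 0.94 across 6226 genes. Those of the other 3 pairs correlated with these less closely, and positively for the library with less Jund RNA minus the other. Genomic DNA in those libraries would be expected to leave genes at 32 CPM or more with a shared spread below 0.1 on the log2 scale, and the smallest spread was 0.479, which excludes DNA as the whole cause. DNA as a part would raise olfactory and vomeronasal receptor genes (1508) in the same library of each pair, and ratios of their summed CPM were 3.11, 1.13 and 2.86. In the other 3 pairs the library with less Jund RNA also had more of these transcripts (5.36 in naive CD4, 2.25 in naive CD8 and 2.91 in activated CD8 cells), and it had more genes detected in all 6 pairs. The bound set before was 1.2, but log2 ratios of the other 3 pairs spread by 0.64 (SD), more than the distance of 1.13 from that bound, a measure of spread chosen after the ratios were seen. DNA as a part was thus left open. Length of the gene span as the whole cause was excluded, since the correlations stayed at 0.94 or more once the trend was removed. No biological explanation was tested, nor, for want of a genome, sequence composition.

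Against the satellite region, counts in Tcf1 peaks were lower in activated than in naive cells. The region's share rose 3.11-fold in CD4 cells (1.89-fold without activated CD4 replicate 2) and 10.8-fold in CD8 cells. Higher background in each activated library would raise this share for Runx1 as well, unless counts in Runx1 peaks rose with it. The Runx1 share rose 1.28-fold in CD8 cells and was 0.893 times the naive share in CD4 cells. Counts in Runx1 peaks were also higher in activated CD4 libraries (11.55 M and 11.95 M against 8.27 M and 8.9 M in naive ones). The share alone thus cannot exclude higher background. Ets1 shares rose 1.85-fold and 3.34-fold. Less Tcf1 in CD8 cells, as for Tcf7 RNA, could give a larger fall there, and the scaled median was lower by a difference of -1.99 between CD8 and CD4 cells. The same difference for Ets1 was -0.98, so that the test does not separate Tcf1 from a shared cause.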
